A study of Mus musculus with 12 samples.

How the data were processed

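RNA of sorted mouse hepatocytes was sequenced in 12 libraries, 3 per group, made with a SMART-Seq Ultra Low Input kit per the labels' protocols. The groups are young diploid, young polyploid, aged diploid and aged polyploid, taken from the sample titles, and the series design states that both fractions came from 3 young and 3 aged mice. The reporter used in the sort is not given in the sources used here.

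The deposited values are raw counts per gene in the layout of featureCounts per the file headers, 1 file per library with 49315 gene IDs; they are whole numbers that sum to different totals. Reads were trimmed with Trimmomatic 0.36, aligned with STAR 2.5.2b to GRCm38 (mm10) and counted with featureCounts of Subread 1.5.2, per the submitters' processing notes. The Ensembl release, the strand setting and whether reads or fragments were counted are not given in the sources used here, so reads of a gene and an overlapping or antisense gene cannot be separated. Total counts per library ranged from 17413153 to 26760570, at which 1 CPM is between 17.4 and 26.8 counts. A level of 0 in a library allows up to 3 counts. Such floors cover counting error only, since reads were not marked by molecular identifiers. Gene IDs were named through GENCODE mouse release M21, in which 49056 IDs matched and 259 did not (0.008% of counts), and 99.91% of matched genes overlapped the position in the files. Symbols carried by more than 1 ID (75) were replaced by the ID.

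Differences were tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16 on the deposited counts, with TMM scaling and 1 mean per group over all 12 libraries. The filterByExpr function kept 14061 of 27518 genes with at least 1 count. A gene passed with a Benjamini-Hochberg adjusted p under 0.05. There were 6 comparisons: aging in each fraction, polyploid against diploid cells in young mice, in aged mice and over both ages, and the interaction of age and ploidy. The 37 gene lists were fixed before the data were examined, and the 33 with at least 5 measured members were tested with camera of limma 3.58.1 with its preset correlation, adjusted over the 33 lists of a comparison. Members were also adjusted over the list alone. Lists not named in the text enter only as a number of lists past the threshold.

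The replicate numbers of the titles were checked as a pairing of the fractions of 1 mouse, which the series design states by its number of mice. Across 8852 genes with a mean CPM of at least 5 (log2 CPM, prior count 1), deviations from the group means correlated between same-numbered libraries with r = 0.444, 0.601 and 0.377 in young and 0.441, 0.499 and 0.492 in aged mice. Each library correlated best with its own number. Between young and aged polyploid libraries, which are different mice, r reached 0.412, so the size of r alone does not mark a mouse. By the best matches and the series design the numbers were taken to mark the mouse. The design without the mouse is the one reported, as planned, and the mouse as a block is given for the ploidy comparisons and the interaction where it changes a call. In the aging comparisons the number is shared by different mice and a block on it pairs nothing.

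Genes were named by a rule set before the data were examined. For each comparison it took the 10 largest changes in each direction among passing genes with a mean of at least 10 CPM in the higher group, non-overlapping replicates and a symbol that is not a model name. For the comparison over both ages the replicates were not to overlap within each age, and for the interaction no such condition was set. Where fewer than 3 qualified, the genes of smallest p, up to 3, were given as values. It also took up to 4 passing members of each list by p, or up to 2 members as values where none passed, and Alb, Cyp2e1, Cyp2f2, Glul, Ccnd1, Cdkn1a, Mki67, Cdk1 and Axin2 in any comparison. A gene that the rule took is not reported here. Gm4788, the genes set apart by age in every library and the genes of largest change within mice were named after their values were seen.

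The alternatives planned were RLE, upper quartile and no scaling factors, no filter and a filter at a mean CPM of 5, DESeq2 1.42.0, limma voom with the mouse as a random effect, robust dispersions, the compared groups alone, the replicate number as a block (the mouse in the ploidy comparisons and the interaction), each library left out in turn, and for lists an estimated correlation and fry. Alternatives chosen after seeing the data were leaving out aged diploid replicates 1 and 2, the log2 sum of endothelial and macrophage markers as a covariate (which parts the compared groups in all comparisons but polyploid aging and shares its genes with those lists), scaling to the hepatocyte identity genes, a loess correction on exon length, each library of the groups not compared left out, and the block combined with leaving out those replicates or with the exon length correction. Leaving out aged diploid replicates 1 and 2 leaves a single aged diploid library, so the spread in those fits comes from the other groups. Paralogs of the Cyp2c, Cyp3a41, Cyp2d9, Saa, Orm, Serpina1, Sult2a and Gm4788 families share sequence, so the split of reads among their members is uncertain.

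The fits were tested on simulated data with 200 of 14061 genes changed in each of the 6 comparisons. The mean of each gene and its spread came from all 12 libraries, fitted without the mouse. edgeR called 5 to 84 of 100 genes changed 4-fold and 0 to 15 of 100 changed 2-fold, with no wrong sign and 3.87% of its calls on unchanged genes. DESeq2 called 36 to 94 of the 4-fold genes, with 29.8% of its calls on unchanged genes. With the block and 10 libraries 0 of 100 4-fold genes were called. Markers of other cells were summed as CPM without TMM factors. No pair of libraries agreed within sampling noise. Alignments and splicing were not analysed here.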

Results

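RNA sequencing libraries were made from hepatocytes, the main cell type of the liver, of C57BL/6 mice aged 3 months (young) or 27 months (aged). The cells were sorted by a reporter and by DNA content into a diploid and a polyploid fraction. Both fractions came from 3 young and 3 aged mice, which gives 4 groups of 3 libraries and 12 libraries in all. Total gene counts ranged from 17413153 in aged polyploid replicate 3 to 26760570 in young diploid replicate 3. The tests covered 14061 genes. Their p-values rest on the spread between libraries within the 4 groups, with no term for the mouse. Both fractions of a mouse entered as independent libraries, although their deviations correlated with r from 0.377 to 0.601. Gene levels are given in CPM scaled by TMM factors, as mean ± SD with n = 3 per group, and the SE beside a log2 fold change is the error of the fit. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those of gene lists from camera.

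Transcripts of other liver cell types were most abundant in the aged diploid libraries and differed widely between them. The summed level of 18 macrophage and Kupffer cell markers was 16830 ± 22570 CPM in aged diploid, 799.8 ± 73.8 in young diploid, 101 ± 77.7 in aged polyploid and 121 ± 92.7 in young polyploid libraries (n = 3 each). In the aged diploid group it was 6512 CPM in replicate 1, 42710 CPM in replicate 2 and 1274 CPM in replicate 3. Endothelial cell markers summed to 3698 ± 4125 CPM in aged diploid and 217.7 ± 2.14 CPM in young diploid libraries. Stellate cell and fibroblast markers summed to 2125 ± 2779 CPM in aged diploid and 46.1 ± 13.2 CPM in young diploid libraries, and MHC class II genes, which present antigen, to 4811 ± 6311 and 197.1 ± 27.2 CPM. B and plasma cell markers summed to 1018 ± 1231 CPM in aged diploid and 13.5 ± 5.25 CPM in young diploid libraries. Aged diploid replicate 2 also had counts in 23354 genes, against 16749 to 20665 in the other 11 libraries. Its 20 most abundant genes took 15.2% of its counts, against 21.5% to 25% in the others, and its TMM factor was 1.70, against 0.836 to 1.14. Albumin, the main secreted protein of hepatocytes, was at 38380 ± 27600 CPM in aged diploid and between 47170 ± 1305 and 52100 ± 2518 CPM in the other groups.

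**Figure D1:**
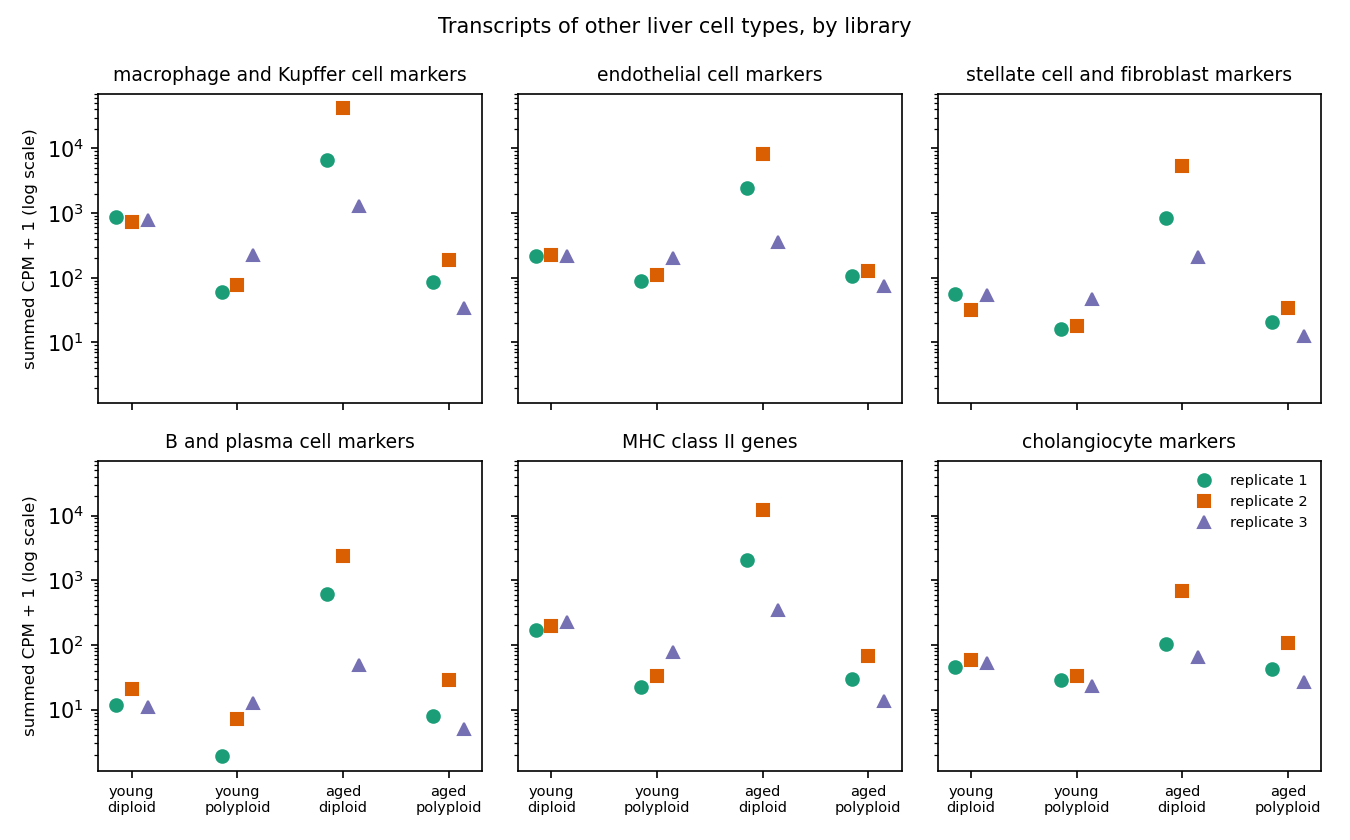
Summed CPM of the markers of other liver cell types in each library, on a log axis, by group. Each point is a library; aged diploid replicate 2 holds 42710 CPM of macrophage and Kupffer cell markers and the aged polyploid libraries average 101 CPM.

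The comparison of polyploid with diploid cells over both ages asks which genes differ with ploidy in the mean of the 2 ages. A gene can pass in it through 1 age alone. In the comparisons within an age 0 genes passed in young and 1363 in aged mice. Cyp2e1, an ethanol- and drug-oxidising enzyme of the hepatocytes around the central vein, was at 1500 ± 555.5 CPM in young diploid and 3314 ± 303.5 CPM in young polyploid cells. In aged mice it was at 1063 ± 712.9 and 4921 ± 1776 CPM, and it rose over both ages by 1.68 on the log2 scale (SE 0.436, adjusted p = 0.0346). Ctsc, a lysosomal protease at 1278 ± 825.9 CPM in the marker-rich aged diploid libraries, and Cdh1 (E-cadherin) fell by 1.46 (SE 0.341, adjusted p = 0.0214) and by 1.29 (SE 0.303, adjusted p = 0.0221) on the log2 scale. They were the passing members of 27 periportal genes, a list that did not pass (10 positive, adjusted p = 0.827). Albumin differed by 0.14 (SE 0.519, adjusted p = 0.877). In all, 124 genes were higher and 1095 lower in polyploid cells.

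Among 27 pericentral hepatocyte genes 7 rose over all genes tested and 11 when adjusted over the list alone, with 26 of 27 positive and a median of 1.06. They included Cyp27a1 of bile acid synthesis at 1.06 (SE 0.236), Cyp2a5 at 1.56 (SE 0.385), Cyp2c54 at 1.26 (SE 0.306), Lhpp at 1.48 and Lect2, a secreted hepatokine, at 1.54. Glul, glutamine synthetase of the innermost pericentral cells, was positive at 0.75 (SE 0.427, adjusted p = 0.263; with the mouse as a block 0.88, adjusted p = 0.0154), and periportal Cyp2f2 was at -0.16 (adjusted p = 0.813). Of 38 xenobiotic metabolism genes 3 rose, and 3 when adjusted over the list alone, with a median of 0.54. Gstp1, a glutathione transferase, rose by 0.94 (SE 0.222, adjusted p = 0.0223) and Aox3, an aldehyde oxidase, by 1.03 (SE 0.277, adjusted p = 0.0399). Of 25 cholesterol synthesis genes 4 rose, among them Mvk at 1.04, Pmvk at 0.73 and Fdps, and 5 did so when adjusted over the list alone. All 25 were positive, with a median of 0.44. Of 31 proteasome genes 4 rose and 16 did so when adjusted over the list alone, with all 31 positive and a median of 0.40. Psmd4 (GRCm38 chromosome 3, 95032694 to 95042614) was at 100.1 ± 2.09 and 156 ± 3.87 CPM in young diploid and polyploid cells and rose by 0.66 (SE 0.165, adjusted p = 0.0295). Scaled to the hepatocyte identity genes, which moved the median of all genes by -0.80, Psmd4 was at -0.13, Psmc4 (0.63) at -0.11, Psmd3 (0.55) at -0.23, and Psmb4 rose by 0.82 under the TMM scaling. Neither of the lists of 34 nuclear oxidative phosphorylation genes (32 positive, median 0.50) and 30 hepatocyte identity genes (27 positive, median 0.46) held a passing member. These lists passed against other genes with adjusted p = 3.78e-11 (pericentral), 1.08e-07 (xenobiotic), 6.01e-06 (cholesterol), 1.97e-08 (proteasome), 3.30e-06 (oxidative phosphorylation) and 0.000188 (hepatocyte identity). None kept the call in the same test with an estimated correlation, where adjusted p = 0.450 for the pericentral and proteasome lists and adjusted p = 0.633 for the other 4. The log2 sum of endothelial and macrophage markers was 9.89 or above in every diploid and 8.74 or below in every polyploid library, so with it as a covariate, chosen after seeing the data, a ploidy difference is an extrapolation. In that fit the proteasome list did not pass (adjusted p = 0.556) and the other 5 turned to the negative direction. Their adjusted p was then 0.163 (pericentral), 1.72e-08 (xenobiotic), 0.00228 (cholesterol), 3.57e-08 (oxidative phosphorylation) and 2.10e-13 (hepatocyte identity).

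Other genes with the largest increase over both ages were Sult2a7 (2.16), Apoc4, an apolipoprotein (1.88), Ang, a secreted ribonuclease (1.38, SE 0.272, adjusted p = 0.00999), Enho (1.31), Fam89a (1.30), Fam25c (1.27) and Adh4, an alcohol dehydrogenase (1.20). Among the genes with the largest fall Cd163, a haptoglobin-hemoglobin receptor of macrophages, was at 8.34 ± 1.94 CPM in young diploid, 0.326 ± 0.344 in young polyploid, 61.6 ± 73.3 in aged diploid and 0.304 ± 0.526 CPM in aged polyploid libraries, and fell by 6.09 (SE 0.934, adjusted p = 0.00616). Fgd2, Cd300e, Dock2, Gbp2b, Dock10, Adgre4, Aoah and P2ry13 changed by between -6.72 and -5.58. Cd300lf was at 0.859 ± 0.35 CPM in young diploid and 0 in all young polyploid libraries. All 18 macrophage and Kupffer cell markers fell (18 adjusted over the list alone, median -4.80), among them Adgre1 (-4.96) and Timd4 (-5.24). All 18 endothelial markers fell (18 adjusted over the list alone, median -2.82), with Mrc1 at -3.65 and Cdh5, vascular cadherin, at -3.22. Of 15 stellate cell and fibroblast markers 11 fell (14 adjusted over the list alone, median -2.97), with Ecm1 at -3.36 and Dcn at -3.65, and 6 of 7 MHC class II genes fell (7 adjusted over the list alone, median -4.16), with H2-Aa at -4.44. The 4 marker lists passed with adjusted p = 2.83e-27, 1.30e-17, 1.92e-11 and 5.65e-10, and for each adjusted p = 0.343 with an estimated correlation.

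The cell cycle genes Mki67 (-1.45, adjusted p = 0.336), Cdk1 (-0.68, adjusted p = 0.561) and Ccnd1 (-0.23, adjusted p = 0.795) did not pass over both ages, nor did the arrest gene Cdkn1a (0.10, adjusted p = 0.857) and the Wnt target Axin2 (0.71, adjusted p = 0.318). With the mouse as a block 3385 genes passed, 1250 higher and 2135 lower, with 16 pericentral, 12 xenobiotic, 14 proteasome, 7 cholesterol synthesis and 14 oxidative phosphorylation genes higher. The count of 1219 was 3540 without aged diploid replicate 3, 673 without aged polyploid replicate 1, 588 without aged polyploid replicate 3, 799 and 726 without young diploid replicates 2 and 3, and 618 and 665 without young polyploid replicates 1 and 2. Fewer genes passed without aged diploid replicates 1 and 2, where a single aged diploid library is left.

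**Figure D2:**
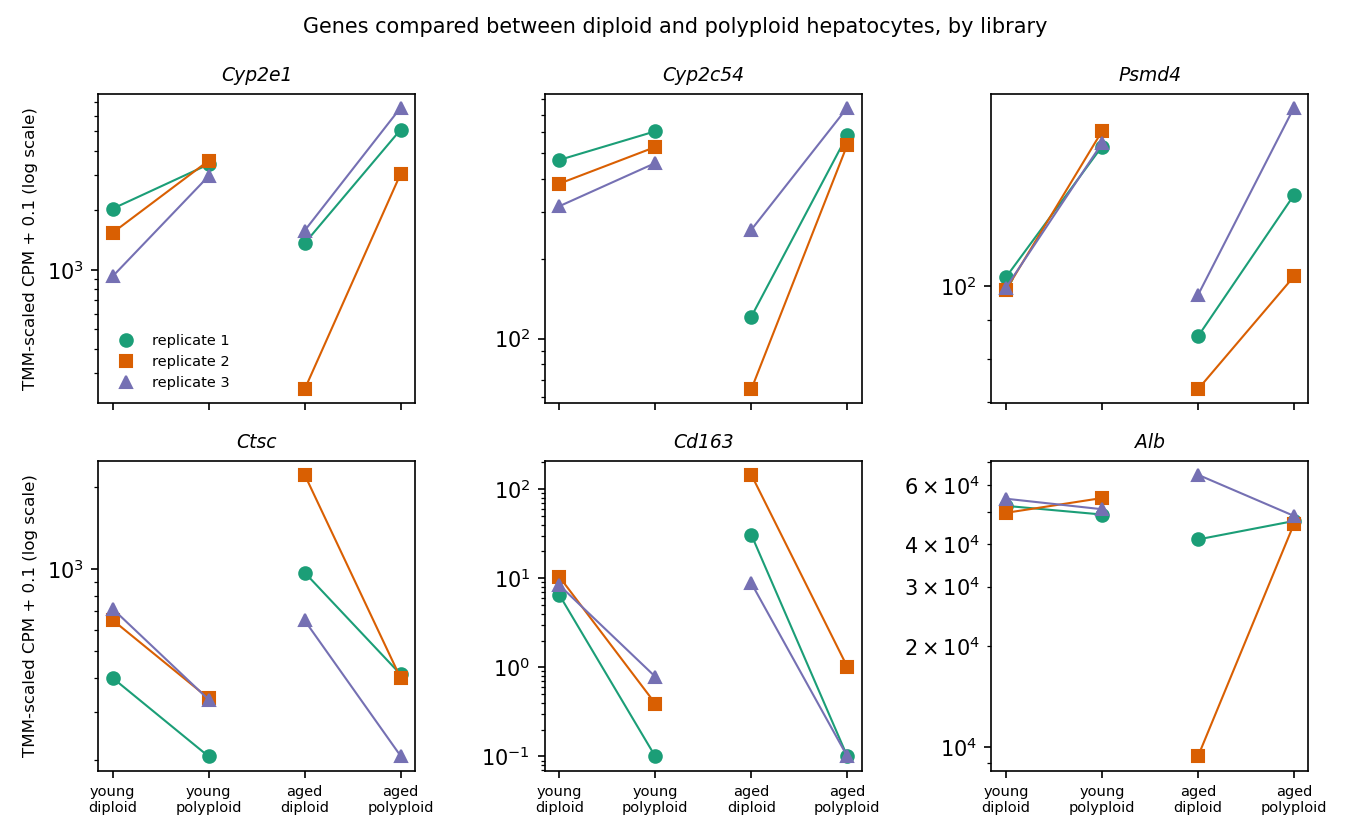
TMM-scaled CPM (log axis) of Cyp2e1, Cyp2c54, Psmd4, Ctsc, Cd163 and Alb in each of the 12 libraries, by group, with lines joining same-numbered libraries of an age. Psmd4 averages 100.1 CPM in young diploid and 156 CPM in young polyploid libraries.

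The comparison within young mice asks how the fractions differ before aging. Macrophage and Kupffer cell markers were lower in the polyploid than in the diploid libraries in 18 of 18 genes with a median of -2.91. Cd163 was at -4.64 (SE 1.27) and Timd4 at -3.41 (SE 0.992), both with adjusted p = 0.393. Genes of the proteasome (25 of 31 positive, median 0.43) and of nuclear oxidative phosphorylation (30 of 34, median 0.44) lay higher in polyploid cells, with Psmd3 at 0.69, Psmd4 at 0.64 and Cox4i1, a subunit of cytochrome oxidase, at 1.10 (SE 0.529). So did 23 of 27 pericentral genes (median 0.44), with Cyp27a1 at 0.77, Lhpp at 1.28, Cyp2e1 at 1.14 (SE 0.609, adjusted p = 0.430) and Glul at 1.12 (SE 0.609, adjusted p = 0.434). No single gene passed in edgeR, where the 4 groups share the spread of a gene. There 1748 had an unadjusted p under 0.05 (734 positive, 1014 negative), and the smallest adjusted p was 0.393. DESeq2 called 76 genes, 12 higher and 64 lower, and the 3 young diploid and 3 young polyploid values did not overlap in 35.8% of genes, against 10% by chance. The smallest p among abundant genes belonged to the phosphatase Pgp (1.08), Acbd6 (0.99) and Smarcb1 (0.87) and, in the other direction, to the kinases Yes1 (-1.22) and Prkci (-1.13) and Slc25a46 (-1.01). Cdkn1a was at 0.74 (adjusted p = 0.477) and Alb at -0.01 (adjusted p = 0.995).

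No member of the young lists passed over all genes tested; adjusted over the list alone 17 macrophage markers were lower. The lists passed in camera with adjusted p = 1.98e-15 (macrophage), 4.74e-05 (proteasome), 0.00037 (oxidative phosphorylation) and 0.000474 (pericentral). Lists of 13 mitochondrially encoded genes (13 positive, median 0.63, adjusted p = 0.0181, with mt-Co3 at 1.24), 7 MHC class II genes (0 positive, median -1.92, adjusted p = 0.00037, with Cd74 and H2-Aa at -2.11 and -2.12), 18 endothelial markers (2 positive, median -0.80, adjusted p = 0.0181) and 17 senescence-associated secreted factors (3 positive, median -0.60, adjusted p = 0.042) passed too. For all 8 adjusted p = 0.977 with an estimated correlation. The fit with the other-cell covariate, an extrapolation here too, turned the pericentral (adjusted p = 0.246) and oxidative phosphorylation lists (adjusted p = 0.0484) negative. The mitochondrially encoded list did not pass with the exon length correction (adjusted p = 0.849). With the mouse as a block 1 gene was higher and 75 lower, 9 of them macrophage markers, with Cd163 at -4.76 (adjusted p = 0.0317), Timd4 at -3.49 (adjusted p = 0.0188) and H2-Aa at -2.22 (adjusted p = 0.0472). Fitted on the young diploid and polyploid libraries alone, 707 genes were higher and 819 lower, and with the mouse as a block and without aged diploid replicates 1 and 2, a fit chosen after seeing the data, 2222 and 2579 were. In simulated data, which held no mouse effect, that fit called 0 of 100 genes changed 4-fold. The simulated spread came from all 12 libraries, including the replicates left out here, so this 0 does not measure the power of the fit. Its aged part is a single pair of libraries, and 0 of 33 lists passed in it with an estimated correlation.

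**Figure D3:**
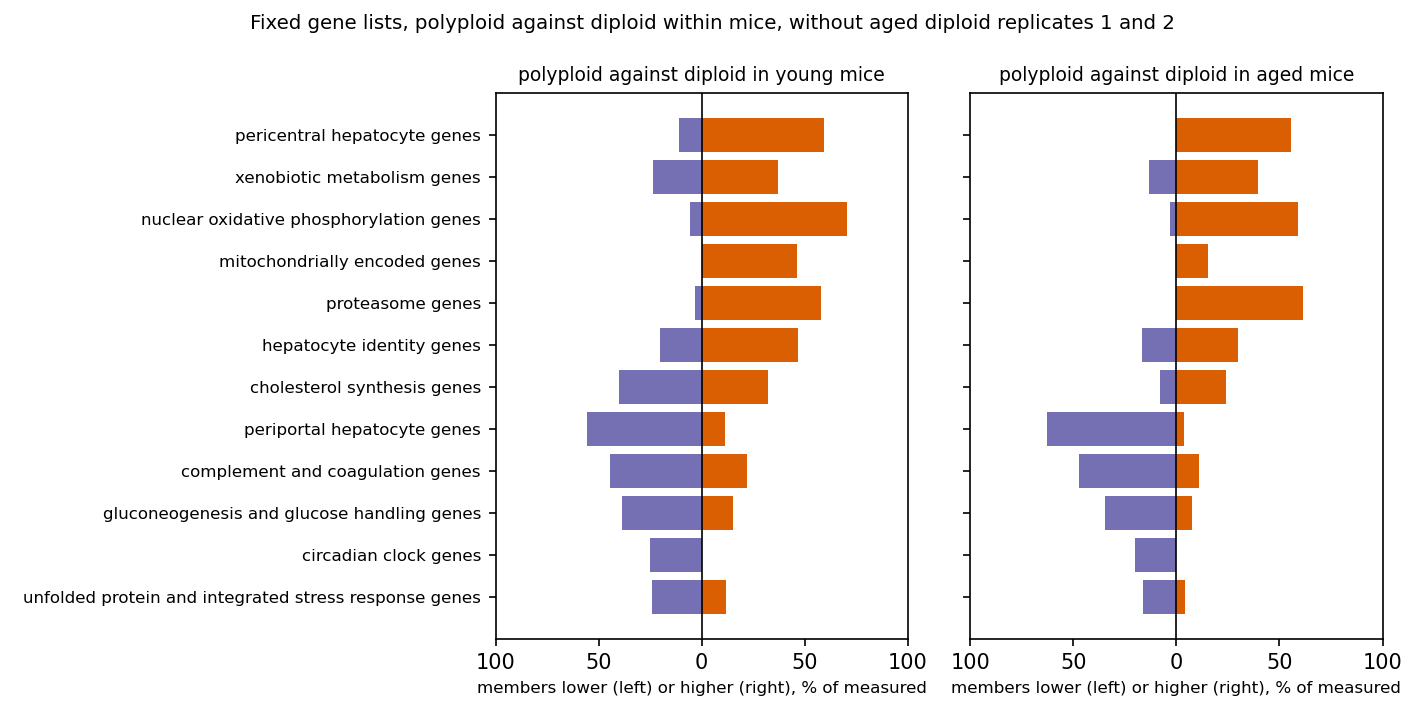
Share of the measured members of fixed gene lists that were higher (right) or lower (left) in polyploid than in diploid cells, with the mouse as a block and without aged diploid replicates 1 and 2. In young mice the pericentral genes had a median log2 change of 0.57 in this fit, while the fit on all 12 libraries called 0 genes in young mice. The aged values come from a single pair.

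The comparison within aged mice asks how the fractions differ late in life. Cyp2c54 (chromosome 19, 40037941 to 40073811), a cytochrome P450 gene, was at 147.5 ± 99.2 CPM in aged diploid and 622.6 ± 107.5 CPM in aged polyploid cells (2.08, SE 0.443, adjusted p = 0.0111). Cyp2a5 passed too, with 108.5 ± 61.1 and 433.6 ± 47.8 CPM. Cyp2c50 rose by 1.90 (SE 0.412), Cyp2c38 by 2.10, Cyp3a41b by 2.08 and Cyp2e1 by 2.21 (SE 0.628, adjusted p = 0.0452) on the log2 scale. Macrophage genes were lower: Lyz2, lysozyme, was at 2556 ± 2986 CPM in aged diploid and 27.1 ± 11.9 CPM in aged polyploid libraries and fell by 6.56 on the log2 scale. In all, 51 genes were higher and 1312 lower in aged polyploid cells.

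All 27 pericentral genes were positive in aged mice (median 1.47). Of these 6 rose and 11 did so when adjusted over the list alone, with Cyp27a1 at 1.35 and Rgn, regucalcin, at 1.85. All 38 xenobiotic metabolism genes were positive (median 0.86), with 3 passing, 4 when adjusted over the list alone and Aox3 at 1.78. All 25 cholesterol synthesis genes were positive (median 0.96), and 3 passed with and without adjustment over the list alone, with Mvk at 1.31 and Pmvk at 1.08. Pmvk was at -0.02 when scaled to the hepatocyte identity genes, which moved the median of all genes by -1.51. Of 25 bile acid synthesis and transport genes 2 rose (3 adjusted over the list alone, median 0.57). All 31 proteasome genes (median 0.51, with Psmd14 at 0.51 and Psmd4 at 0.67), 34 oxidative phosphorylation genes (median 0.54) and 30 hepatocyte identity genes (median 0.64) were positive, and none of them passed. Adjusted p was 2.49e-13 (pericentral), 2.04e-11 (xenobiotic), 7.68e-11 (cholesterol), 1.95e-06 (bile acid), 1.11e-07 (proteasome), 1.59e-05 (oxidative phosphorylation) and 2.71e-06 (hepatocyte identity). With an estimated correlation adjusted p was 0.358 for the pericentral list and adjusted p = 0.397 to 0.537 for the other 6. Under the other-cell covariate, which parts the aged fractions, the proteasome list did not pass (adjusted p = 0.988) and the other 6 turned negative, with adjusted p = 0.164 (pericentral), 8.04e-08 (xenobiotic), 0.046 (cholesterol), 6.09e-06 (bile acid), 4.78e-12 (oxidative phosphorylation) and 3.34e-14 (hepatocyte identity). Further genes with large increases were Sult2a7 (3.01), Hamp, the iron hormone hepcidin (2.58), the acute phase gene Saa2 (2.43), Akr1c6 (2.37) and Hectd2os (2.11). Glul (0.38, adjusted p = 0.724) and Alb (0.30, adjusted p = 0.825) did not pass.

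Every macrophage (18), endothelial (18) and MHC class II (7) marker fell in aged polyploid against aged diploid libraries, with the same numbers when adjusted over the list alone, and medians were -6.87, -4.83 and -6.41. Adgre1 was at -6.95, Cd68 at -7.13, C1qb at -6.73, Cdh5 at -5.68, Dnase1l3 at -4.82 and H2-Ab1 at -6.41. Of 15 stellate cell and fibroblast markers 13 fell (15 adjusted over the list alone, median -5.74), with Dcn at -6.40 and Ecm1 at -6.20, and of 8 B and plasma cell markers 4 did (7 adjusted over the list alone, median -5.76). These 5 lists passed with adjusted p = 3.10e-23, 3.10e-23, 1.14e-09, 1.02e-16 and 0.000105, and for each adjusted p = 0.234 with an estimated correlation. Of 17 senescence-associated secreted factors 9 fell (11 adjusted over the list alone, median -4.91, adjusted p = 5.98e-06), among them Igfbp3 (-5.29) and Igfbp7 (-5.18). Of 17 fetal or dedifferentiated liver genes 7 fell (10 adjusted over the list alone, median -1.99, adjusted p = 0.000572), among them Vim (-5.85), and of 45 interferon-stimulated genes 5 fell (7 adjusted over the list alone, median -0.99, adjusted p = 0.00386). For these 3 lists adjusted p = 0.303, adjusted p = 0.397 and adjusted p = 0.734 with an estimated correlation. Under the covariate, with the same limit, they turned positive (adjusted p = 0.303, 0.0709 and 5.49e-27), and the interferon list did so without aged diploid replicate 2 (adjusted p = 0.998) and without aged diploid replicates 1 and 2 (adjusted p = 0.142) as well. In the same libraries the macrophage markers summed to 16830 CPM in aged diploid and 101 CPM in aged polyploid cells. The genes with the largest falls had mean levels between 0.0159 CPM (Cd40) and 0.0639 CPM (Ms4a6b and Ifi213) in aged polyploid libraries. They were Cd40, a receptor of B cells and macrophages (10.7 ± 12.2 CPM in aged diploid libraries), Tlr13, Ms4a7, Ms4a6b, Pmaip1, Slamf8, Tmc3, Adgb, Sash3 and Ifi213 (15.3 ± 22.7 CPM). Ctsc was at -1.91 and Cdh1 at -1.60.

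The aged count of 1363 rested on single libraries: it was 816 without aged diploid replicate 2, 3218 without aged diploid replicate 3, 871 without aged polyploid replicate 2 and 0 without aged polyploid replicate 1 or 3. It was 0 in a fit on the aged libraries alone. With the mouse as a block 494 genes were higher and 1720 lower, with 15 pericentral, 12 xenobiotic and 7 cholesterol synthesis genes higher. Without aged diploid replicates 1 and 2 a single aged diploid library is left, and calls in that fit do not measure the spread of the group. There the aged lists for oxidative phosphorylation, hepatocyte identity and bile acids did not pass. In all 12 libraries proteasome genes had adjusted p = 0.0627 when scaled to the hepatocyte identity genes.

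The comparison of aged with young polyploid cells asks what aging changes in polyploid hepatocytes, where markers of other cells were low at both ages. Cyp2c39 (chromosome 19, 39510862 to 39568529), a cytochrome P450 gene, was at 5.39 ± 1.95 CPM in young and 519.3 ± 202 CPM in aged polyploid cells and rose by 6.59 on the log2 scale (SE 0.596, adjusted p = 0.00181), with the sharing of reads among Cyp2c genes uncertain. Metap1d (chromosome 2, 71453276 to 71525194), a mitochondrial methionine aminopeptidase, was at 0.374 ± 0.268 and 28 ± 11.7 CPM and rose by 6.26 (SE 0.650, adjusted p = 0.00405). Camk1d (chromosome 2, 5293457 to 5714515), a calcium/calmodulin-dependent kinase, was at 12.8 ± 3.63 and 69.3 ± 20 CPM and rose by 2.44 (SE 0.299, adjusted p = 0.0114). Pls1 (chromosome 9, 95752642 to 95845311), an actin-bundling plastin, was at 7.03 ± 1.08 and 0.666 ± 0.446 CPM and fell by 3.36 (SE 0.483, adjusted p = 0.0451). A predicted gene, Gm4788 (chromosome 1, 139697623 to 139781243), named here after its values were seen, rose by 4.97 (SE 0.556, adjusted p = 0.0059). These 5 genes, 4 higher and 1 lower, were all that passed, and for each of them the libraries of both ages were apart. Young and aged mice were different animals, so age cannot be told apart from other differences between them, such as genotype.

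Wnt/beta-catenin target genes were positive in 11 of 11 in aged polyploid cells, with a median of 1.55. None passed over all genes and 5 were higher when adjusted over the list alone, with Tbx3 at 2.03 (SE 0.657) and Axin2 at 1.93 (SE 0.646, adjusted p = 0.417) at 0.225 ± 0.101 CPM in young and 0.864 ± 0.501 CPM in aged cells. Dkk3 was at 0 in all young polyploid libraries and 0.509 ± 0.118 CPM in aged ones. Of 27 pericentral genes 22 were positive (3 adjusted over the list alone, median 0.63), with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 2.81 and the glutamate transporter Slc1a2 at 3.12. Periportal genes were mostly negative, with 6 of 27 positive (1 lower adjusted over the list alone, median -0.41) and Cdh1 at -2.07 (adjusted p = 0.189). Of 34 nuclear oxidative phosphorylation genes 2 were positive (median -0.54), with Cox5a at -0.69 and Cox8a at -0.66, and of 13 mitochondrially encoded genes 0 were (median -0.54), with mt-Nd2 at -0.84. Female-biased liver genes were positive in 18 of 26 (5 adjusted over the list alone, median 0.50), with Cyp3a41a and Cyp3a41b at 2.51 and 2.73. G2/M and cytokinesis genes were positive in 33 of 34 (median 1.83), at low levels such as 1.38 ± 2.06 CPM for Mki67 in aged polyploid cells, and endothelial markers in 2 of 18 (median -0.63). The 8 lists passed with adjusted p = 2.00e-07 (Wnt), 0.00156 (pericentral, periportal and mitochondrially encoded), 2.90e-08 (oxidative phosphorylation), 0.000359 (female-biased), 0.00452 (G2/M) and 0.0073 (endothelial). With an estimated correlation adjusted p = 0.231 for the Wnt list and adjusted p = 0.832 for the other 7. Dbp, an output gene of the circadian clock (-3.57), Pdk4, a pyruvate dehydrogenase kinase (1.93), both with adjusted p = 0.089, Cyp2d9 (-2.31, adjusted p = 0.185) and Pnpla2, a triglyceride lipase (-0.90, adjusted p = 0.227), did not pass, nor did Glul (0.98), Cyp2e1 (0.57), Alb (-0.13) and Cdkn1a (-0.33).

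At an unadjusted p under 0.05 there were 1289 genes in polyploid aging. The count of 5 was 37 without aged diploid replicate 2, which shares the fit, 17 without aged polyploid replicate 3, 3 without aged polyploid replicate 1 or young polyploid replicate 1, and 1 without young polyploid replicate 2 or 3. It was 39 (29 higher, 10 lower) without aged diploid replicates 1 and 2, and of the 5 genes Cyp2c39 passed under all 26 alternatives. The calls were 80% higher under TMM and 100% under library size alone, upper quartile scaling and scaling to the hepatocyte identity genes.

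**Figure D4:**
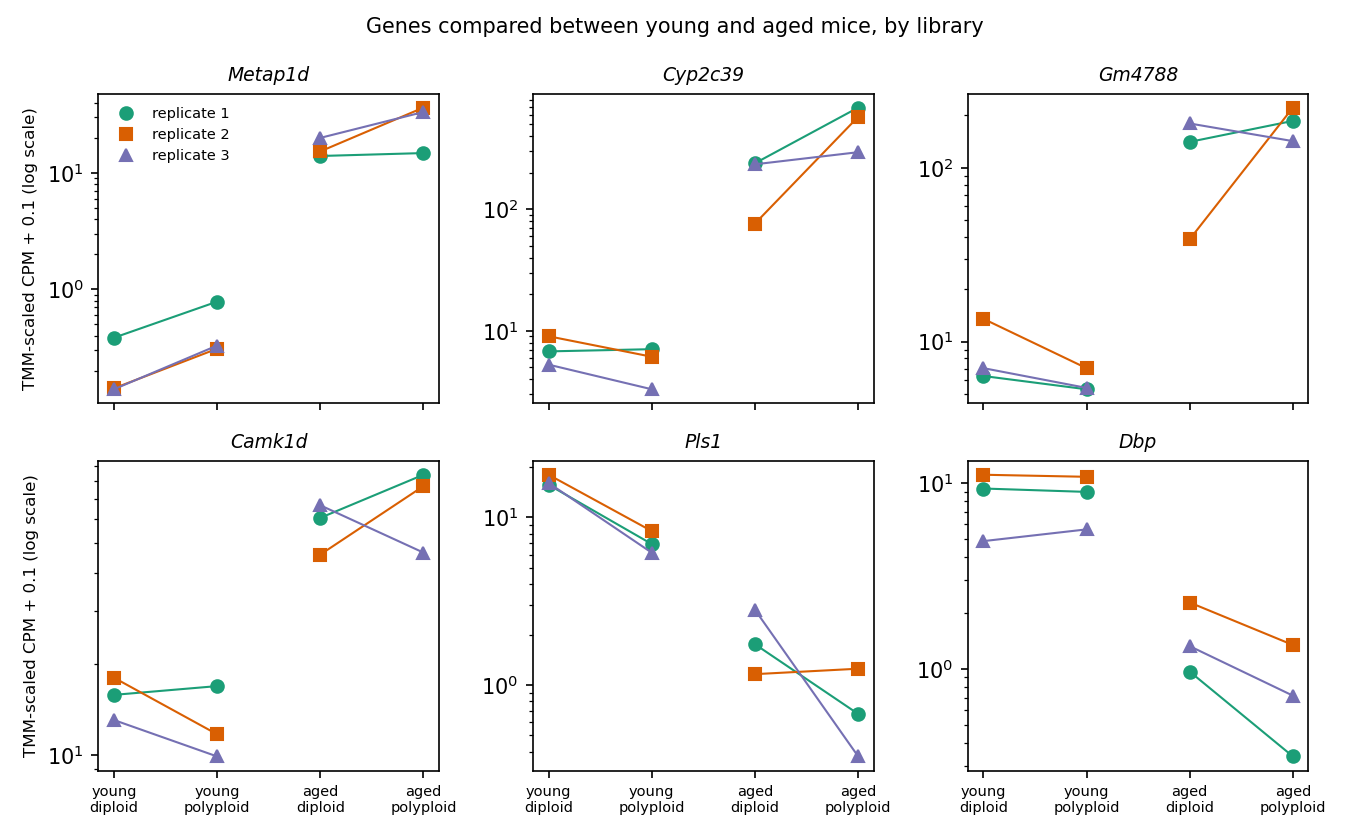
TMM-scaled CPM (log axis) of Metap1d, Cyp2c39, Gm4788, Camk1d, Pls1 and Dbp in each of the 12 libraries, by group, with lines joining same-numbered libraries of an age. Cyp2c39 averages 6.91 and 5.39 CPM in young diploid and polyploid cells and 183.2 and 519.3 CPM in aged ones.

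The comparison of aged with young diploid cells asks what aging changes in diploid hepatocytes. Cyp2c39 was at 6.91 ± 1.89 CPM in young and 183.2 ± 92.7 CPM in aged diploid cells (4.73, SE 0.545, adjusted p = 0.0122), and Metap1d at 0.121 ± 0.141 and 16.3 ± 3.15 CPM (7.08, SE 0.705, adjusted p = 0.00513). Pls1 fell by 3.19 on the log2 scale (SE 0.461, adjusted p = 0.0490), from 16.5 ± 1.24 to 1.81 ± 0.835 CPM. Genes of plasma cells were higher in aged diploid libraries, with the immunoglobulin genes Ighm at 102.1 ± 116.1 CPM against 0.693 ± 0.368 CPM and Igkc at 283.1 ± 310.4 against 4.17 ± 3.62 CPM. In all, 528 genes were higher and 24 lower. As in polyploid cells, age cannot be told apart from other differences between the young and the aged mice.

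Acute phase genes were among the 24 lower genes of aged diploid cells. Of 32 acute phase genes 3 fell (2 higher and 4 lower adjusted over the list alone, median -0.50), namely Saa2 at -2.46, Orm3 at -2.43 and Mt2, a metallothionein, at -1.34 (SE 0.317). Serpina1e, an alpha-1-antitrypsin gene, was at -2.15, and the apolipoprotein gene Apoa4, the passing member of 27 periportal genes (1 lower adjusted over the list alone, 2 positive, median -0.69), at -2.13. Cyp2d9 was at -2.94. Trib3 (-1.94), Insc (-1.78) and Hspb8 (-1.40) were lower too. Of 19 circadian clock genes 2 fell, Dbp (-2.54) and Nr1d2 (-1.26), and 3 when adjusted over the list alone, with a list median of -0.49. None passed among 25 cholesterol synthesis genes (0 positive, median -0.89), 34 oxidative phosphorylation genes (0 positive, median -0.64) and 30 hepatocyte identity genes (1 positive, median -0.51). These lists passed with adjusted p = 3.01e-05 (acute phase), 6.37e-08 (periportal), 0.000257 (circadian), 1.18e-12 (cholesterol), 1.10e-10 (oxidative phosphorylation) and 7.82e-07 (hepatocyte identity). With an estimated correlation adjusted p = 0.385 for the acute phase, circadian and cholesterol lists and adjusted p = 0.393 for the other 3. The other-cell covariate, at 10.7 or above in every aged and 10.1 or below in every young diploid library and so an extrapolation as well, turned the periportal (adjusted p = 0.312), oxidative phosphorylation (adjusted p = 0.309) and hepatocyte identity lists (adjusted p = 1.61e-05) positive. Cyp2e1 (-0.50, SE 0.602) and Alb (-0.44, SE 0.735) did not pass in diploid aging. Changes in diploid aging rose with exon length across genes too (Spearman rho = 0.191), which these values do not separate from aging in the lists.

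Of 18 endothelial markers 15 rose in aged diploid libraries (18 adjusted over the list alone, median 3.46), with Ehd3 at 4.01 and Dnase1l3 at 3.49. Of 15 stellate cell and fibroblast markers 10 rose (14 adjusted over the list alone, median 4.70), with Reln at 5.57, Dcn at 5.13 and Ecm1 at 5.08. Of 18 macrophage and Kupffer cell markers 4 rose (17 adjusted over the list alone, median 3.65), with Cd68 at 4.24, Clec4f at 4.18 and Cd5l at 3.95. Of 7 MHC class II genes 6 rose (7 adjusted over the list alone, median 4.07), with H2-Eb1 at 4.15 and H2-Ab1 at 3.98. Of 8 B and plasma cell markers 3 rose (6 adjusted over the list alone, median 5.98), with Ighm at 7.21, Igkc at 6.08 and Jchain at 5.87. The lists passed with adjusted p = 3.93e-16, 5.13e-15, 7.96e-10, 5.56e-06 and 4.64e-05, and adjusted p = 0.385 with an estimated correlation for each. Of 17 senescence-associated secreted factors 3 rose (12 adjusted over the list alone, median 2.77, adjusted p = 0.000255), Igfbp3 at 3.21, Igfbp7 at 3.80 and Hgf, hepatocyte growth factor, at 4.30. Of 45 interferon-stimulated genes 1 rose (10 adjusted over the list alone, median 0.92, adjusted p = 4.75e-05). With an estimated correlation adjusted p = 0.385 for the secreted factors and adjusted p = 0.540 for the interferon list. The secreted factor (adjusted p = 0.606) and interferon lists (adjusted p = 2.99e-10) turned negative under that covariate. Vim (3.79), Tmsb10 (3.80), Anxa2 (3.23), Trem2 (6.05), Gdf3 (7.23), Gem (6.48), Enpp6 (6.21), S1pr3 (6.09) and Dkk3 (5.82) rose as well, and in the same libraries macrophage markers summed to 6512, 42710 and 1274 CPM in replicates 1 to 3. Ccnd1 (2.35, adjusted p = 0.0913), Glul (1.72, adjusted p = 0.134), Cdkn1a (0.95, adjusted p = 0.286) and Mki67 (2.72, adjusted p = 0.304) did not pass.

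Young and aged libraries were apart in 506 of the 528 higher genes of diploid aging and in all 24 lower genes, and in 20.9% of all genes tested against 10% by chance. Most adjusted p-values stood at 0.0490 to 0.0492, and the count of 552 was 1 without aged diploid replicate 1, 13 without aged diploid replicate 2, 2974 without aged diploid replicate 3, 1 without young diploid replicate 1 and 0 without young diploid replicate 2 or 3. Without a library that only shares the fit it was 2, 3 and 3 (aged polyploid replicates 1 to 3) and 2 (each young polyploid replicate). Without aged diploid replicates 1 and 2 the aged diploid group is replicate 3 alone, and the spread comes from the other groups. There the hepatocyte identity, oxidative phosphorylation and periportal lists did not pass, and the stellate, endothelial and macrophage lists did. A single library cannot decide between these lists. In all 12 libraries the stellate, endothelial and macrophage lists had adjusted p = 0.385 with an estimated correlation. Of the calls 95.7% were higher under TMM, 75% of 4 under RLE and 66.7% of 6 with the exon length correction. Library size alone moved the median of all genes by 0.38 in diploid aging, by 0.16 in polyploid aging and by -0.17, -0.38, -0.27 and -0.22 in the young, aged, both-age and interaction comparisons. Scaling to the hepatocyte identity genes moved it by 1.43, 0.06, -0.15, -1.51, -0.80 and -1.35 in that order.

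The interaction of age with ploidy asks whether aging differs between the fractions. All 25 cholesterol synthesis genes were positive (median 0.95), with aging values higher in polyploid than in diploid cells, as in Idi1 (1.86, SE 0.631, adjusted p = 0.303) and Hmgcs1 (2.01, SE 0.769, adjusted p = 0.358). Of 27 pericentral genes 25 were positive (median 0.88), with Cyp2c50 at 1.66 (SE 0.567, adjusted p = 0.304) and Cyp2c54 at 1.64 (SE 0.606, adjusted p = 0.343). All endothelial (18), macrophage (18), stellate (15) and MHC class II (7) markers were negative, with medians of -4.17, -4.12, -4.76 and -4.49, and 18, 17, 12 and 6 were lower when adjusted over the list alone. Adcy4 was at -4.94, Cdh5 at -4.92 and Ecm1, a matrix protein of stellate cells, at -5.69, all with adjusted p = 0.249. Among positive genes at 10 CPM or more in a group, model names aside, Zfp946 (1.35), Cul4b (1.24) and Slc25a46 (1.17) had the smallest p. No gene passed in edgeR, with 1545 at an unadjusted p under 0.05 (323 positive, 1222 negative), and DESeq2 called 24 higher and 465 lower. With the mouse as a block 2 genes were higher and 187 lower, among them Adcy4 (-4.50, adjusted p = 0.0424), Cdh5 (-4.66, adjusted p = 0.0314) and Ecm1 (-4.88, adjusted p = 0.0361), and without aged diploid replicate 3 edgeR called 762. Adjusted p of the lists was 8.23e-10 (cholesterol), 2.78e-06 (pericentral), 2.84e-24 (endothelial), 1.89e-14 (macrophage), 3.19e-18 (stellate) and 1.63e-07 (MHC class II). With an estimated correlation adjusted p = 0.520, 0.530, 0.370, 0.401, 0.370 and 0.401 in that order. Without aged diploid replicates 1 and 2, which leaves a single aged diploid library, the pericentral list did not pass. Under the other-cell covariate, which parts the diploid from the polyploid libraries, that list had adjusted p = 0.499 in the negative direction.

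The same genes were called by aging in both fractions 5 times: Cyp2c39, Metap1d, Gm4788 and Camk1d were higher in both, against 0.15 shared genes for independent lists, and Pls1 was lower in both, against 0.00171. The fractions come from the same mice, so differences between mice enter both comparisons. Across genes, which are not independent replicates, the aging changes of the fractions had Pearson r = 0.205 and Spearman rho = 0.238. That r was -0.0381 without aged polyploid replicate 2, 0.325 without young polyploid replicate 3, 0.134 without aged diploid replicates 1 and 2 and 0.1 without a filter on low counts. The overlap of 5 was 1 without young diploid replicate 1, 0 without young diploid replicate 2 or 3, 1 without aged diploid replicate 1, 11 without aged diploid replicate 2, 2, 3 and 3 without aged polyploid replicates 1 to 3, and 2, 1 and 1 without young polyploid replicates 1 to 3. The ploidy comparisons of young and aged mice shared no called gene, since none passed in young mice, and their changes had r = 0.593 and rho = 0.518 across genes, with r = 0.327 (rho = 0.290) without aged diploid replicates 1 and 2 and r = 0.276 without a filter on low counts. With the mouse as a block they shared 74 genes, 1 higher (0.0351 for independent lists) and 73 lower (9.17 for independent lists).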

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

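The test of the hepatocyte identity genes in aged diploid replicate 2 was chosen only after the result was seen. The results in this part stood out because aging differed between the polyploid and the diploid fraction, by the test of the interaction. With the mouse as a block 2 genes were higher and 187 lower in the interaction, and without it 0 passed. Of 33 gene lists 22 passed, and 0 did so with an estimated correlation. The median log2 interaction was 0.951 for cholesterol synthesis genes, -4.17 for endothelial, -4.12 for macrophage and Kupffer cell and -4.76 for stellate cell and fibroblast markers, and -4.49 for MHC class II genes. The adjusted p of these lists with an estimated correlation was 0.520, 0.370, 0.401, 0.370 and 0.401. The 10 splits of the 6 mice are too few for a share under 0.05, with 189 genes under the block for the ages as they are and at most 0 in the other splits, and with 22 lists against at most 24.

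The markers behind these negative interactions were higher in the aged diploid libraries, with Lyz2 at 2556 ± 2986, Cd74 at 1565 ± 1751 and Clec4f at 1382 ± 1665 CPM, and all 30 hepatocyte identity genes were lower in aged diploid replicate 2 than in the mean of replicates 1 and 3. Their median log2 ratio was -1.93 (quartiles -2.17 and -1.72), as the hypothesis of cells of other types, or their RNA, in the diploid sort predicts. No stricter sort was tested. Of the 18 macrophage, 18 endothelial, 15 stellate and 7 MHC class II genes tested, 0 are held by another of the lists, and 10, 10, 2 and 3 average at least 5 CPM in young polyploid hepatocytes too. A lower hepatocyte share with the mix of other cells unchanged predicts like list medians in diploid aging. They were 3.65, 3.42, 4.64 and 4.04 over the 18, 17, 8 and 6 members at 1 CPM or more in young diploid libraries. Their widest difference of 1.22 had a permutation p of 6e-04 over 10000 draws, which shuffle genes and not mice. Endothelial markers also summed to 131.1 CPM in young polyploid against 217.7 CPM in young diploid libraries. A level present without these cells lowers a fold change, so the test cannot decide. A change with age in these cells or in diploid hepatocytes stays open and was not tested.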

How the results depend on the processing

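The tests chosen only after the results were seen are those without aged diploid replicates 1 and 2, with the other-cell marker covariate, with the scaling to hepatocyte identity genes, with the exon length correction, with these joined to the block, and those leaving out a library of a group not compared. Numbers of genes past the threshold are given below in the order diploid aging, polyploid aging, young, aged, both ages and interaction, where the reported numbers were 552, 5, 0, 1363, 1219 and 0, and only where they moved by over 1.5 times. The cause of these moves was not tested, except that dropping the filter or a library changes the genes or samples in the fit by construction. Leaving out aged diploid replicates 1 and 2 leaves a single aged diploid library, so values from those fits do not measure the spread of that group. In the reported fit, with 3 mice per group and a spread per gene shared by the 4 groups, a gene needed a large change to pass. Fitted alone, with the same 3 mice per group, the young libraries gave many genes past the threshold (below). Group size by itself therefore did not set their 0. At these depths 1 CPM is between 17.4 and 26.8 counts.

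Without a filter on low counts the numbers were 2023, 61, 144, 2384, 2431 and 690, and at a mean CPM of at least 5 they were 5 in diploid aging, 785 in aged and 721 over both ages. DESeq2 gave 1643, 152, 76 (young), 2454 (both ages) and 489 (interaction). In diploid aging RLE factors gave 4, upper quartile scaling 2 and robust dispersions 2, and limma voom gave 7 there and 230 in aged mice. Fits on the compared groups alone gave 0 in diploid aging, 13 in polyploid aging, 1526 in young and 0 in aged mice. The replicate block of the mouse gave 76, 2214, 3385 and 189 in the last 4 comparisons. The call of Glul over both ages, of Cd163, Timd4 and H2-Aa in young mice and of Adcy4, Cdh5 and Ecm1 in the interaction came with that block. In aging different mice share a replicate number, so the block pairs nothing there: it gave 0 in diploid and 42 in polyploid aging, where same-numbered libraries correlated with r from -0.31 to 0.22 and none best with its own number. Without aged diploid replicates 1 and 2 the numbers were 3, 39, 1 (aged) and 261 (both ages). The other-cell covariate gave 6, 34, 2, 0 and 0 in the first 5 comparisons, the hepatocyte scaling 1075 in diploid and 2 in polyploid aging, and the exon length correction 6 and 8. The exon length correction with the block gave 43 in young mice, 2553 over both ages and 160 in the interaction, and the block without aged diploid replicates 1 and 2 gave 4801, 2820, 5483 and 34 in the last 4 comparisons. Leaving out 1 library at a time gave 0 to 2974 in diploid aging, with 1, 13 and 2974 without aged diploid replicates 1, 2 and 3, and 0 without young diploid replicate 2 or 3. It gave 1 to 37 in polyploid aging (37 without aged diploid replicate 2, 1 without young polyploid replicate 2 or 3), 0 to 0 in young mice and 0 to 762 in the interaction (762 without aged diploid replicate 3). It gave 0 to 3218 in aged mice (0 without aged polyploid replicate 1 or 3, 3218 without aged diploid replicate 3) and 588 to 3540 over both ages (588 without aged polyploid replicate 3, 3540 without aged diploid replicate 3).

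Of 33 gene lists 26, 8, 8, 23, 25 and 22 passed in the 6 comparisons. An estimated correlation left 0 in each. The directional fry test left 0, 0, 0, 8, 7 and 0, and its mixed test 4, 2 and 0 in the first 3, 13 over both ages and 0 in the interaction. Without aged diploid replicates 1 and 2 the number was 13 in diploid aging, 15 in aged mice, 13 over both ages and 10 in the interaction. Without aged diploid replicate 2 it was 22, 8, 8, 19, 13 and 12. The hepatocyte scaling gave 13 in polyploid aging, and the other-cell covariate 13 in polyploid aging, 20 in young mice and 14 in the interaction.

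Aging of both fractions shared 5 genes. It was 2 with upper quartile scaling, 41 without a filter, 51 in DESeq2, 3 in limma voom, 2 with robust dispersions, 0 with the compared groups alone, 0 with the block on the replicate number, 3 without aged diploid replicates 1 and 2, 2 with the hepatocyte scaling, and 0 to 11 with 1 library left out (0 without young diploid replicate 2 or 3, 11 without aged diploid replicate 2). The ploidy comparisons of young and aged mice shared 0 genes, 137 without a filter, 37 in DESeq2, 74 with the replicate block, 43 with the exon length correction and the block, 2167 with the block and without aged diploid replicates 1 and 2, and 0 to 0 with 1 library left out.

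Of the directions of the lists named in a comparison of the report, 29 turned under the other-cell covariate, 34 turned in all, and the cause was not tested. The covariate parts the groups in all comparisons but polyploid aging and is the sum of endothelial and macrophage markers, so its values are extrapolations and for those lists condition on the outcome. With the covariate the adjusted p of the turned lists was, in diploid aging, 0.00406 (macrophage), 0.309 (oxidative phosphorylation), 0.312 (periportal), 1.61e-05 (hepatocyte identity), 0.606 (secreted factors) and 2.99e-10 (interferon). In young mice it was 0.246 (pericentral), 0.0484 (oxidative phosphorylation), 3.85e-06 (endothelial) and 0.165 (secreted factors). In aged mice it was 0.164 (pericentral), 8.04e-08 (xenobiotic), 0.046 (cholesterol), 6.09e-06 (bile acid), 4.78e-12 (oxidative phosphorylation), 3.34e-14 (hepatocyte identity), 0.85 (endothelial), 0.303 (secreted factors), 0.0709 (fetal genes) and 5.49e-27 (interferon). Over both ages it was 0.163 (pericentral), 1.72e-08 (xenobiotic), 0.00228 (cholesterol), 3.57e-08 (oxidative phosphorylation), 2.1e-13 (hepatocyte identity), 0.0215 (endothelial) and 0.558 (stellate), and in the interaction 0.499 (pericentral) and 0.612 (macrophage). Without aged diploid replicates 1 and 2 it was 0.412 (hepatocyte identity) and 0.603 (interferon) in diploid aging and 0.805 (oxidative phosphorylation) and 0.142 (interferon) in aged mice, and without aged diploid replicate 2 alone 0.998 (interferon) in aged mice.

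Among named genes, of 1163, 618, 560, 1228, 1320 and 270 pairs of gene and setting in the 6 comparisons, 362, 544, 501, 933, 1026 and 246 kept direction and side of the threshold. Of the passing genes, 0 of 39, 1 of 5, 0 of 40 and 0 of 41 in diploid aging, polyploid aging, aged mice and both ages did so in all settings. The log2 change turned with the covariate in aged mice in Sult2a7 (-0.42), Cyp2e1 (-0.39), Cyp2a5 (-0.0640), Tmc3 (0.00862), Ifi213 (0.43), Rgn (-0.0875), Mvk (-0.33), Pmvk (-0.00593), Ctsc (0.30) and Igfbp7 (0.38). Over both ages it turned in Sult2a7 (-0.28), Apoc4 (-0.0769), Cyp2e1 (-0.17), Lect2 (-0.41), Fam89a (-0.00609), Fam25c (-0.40), Cyp2c54 (-0.10), Mvk (-0.12), Pmvk (-0.0294), Fdps (-0.27) and Ctsc (0.0300). With the hepatocyte scaling it turned in Pmvk (-0.0210) in aged mice and in Psmd4 (-0.13), Psmc4 (-0.11) and Psmd3 (-0.23) over both ages, by less than the shift of all genes there.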

Other observations

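The tests in this part chosen only after the results were seen are the fit within mice without aged diploid replicates 1 and 2, those of the genes set apart by age, those of dilution, of exon length, of the ribosomal protein genes, a set formed after seeing the data, and the numbers of lists in the splits that part every pair. In that fit the young values come from 3 pairs of libraries and the aged ones from mouse 3 alone. In simulated data, which held no mouse effect, it called 0 of 100 genes changed 4-fold. The simulated spread came from all 12 libraries, including the replicates left out here, so this 0 does not measure the power of the fit. The calls of the fit are to be read with caution. Within young mice the liver zones parted: 16 of 27 pericentral genes were higher in polyploid cells and 3 lower (median 0.57, adjusted p = 3.24e-09), while 3 of 27 periportal genes were higher and 15 lower (median -0.34, adjusted p = 0.000949). Of 34 nuclear oxidative phosphorylation genes 24 were higher and 2 lower (median 0.43, adjusted p = 1.97e-11), with Cox4i1 at 1.09 and Uqcrq at 1.22, and of 31 proteasome genes 18 were higher and 1 lower (adjusted p = 5.94e-08). The estimated correlation gave adjusted p = 0.480 for oxidative phosphorylation and adjusted p = 0.747 for the other 3 lists. In all 12 libraries without the block the periportal list (adjusted p = 0.335) lay in the same direction and did not pass, nor did any gene. Among the genes of smallest p, named after their values were seen, were Mir6236 (1.74, adjusted p = 9.54e-06), Lars2 (1.49, adjusted p = 1.94e-05), the apolipoprotein genes Apoc4 (1.25, SE 0.0813, adjusted p = 1.94e-05) and Apoa2 (0.88), the glutathione peroxidase Gpx1 (0.88) and, lower in polyploid cells, the proteoglycan Sdc3 (-3.26, SE 0.182, adjusted p = 9.54e-06), the protease inhibitor Pzp (-0.90), the iron exporter Slc40a1 (-1.13), the growth factor receptor Fgfr2 (-1.26) and complement component Hc (-0.90). The share of counts in annotated rRNA and mitochondrial tRNA genes was higher in the polyploid than in the diploid library of each young mouse (0.0362% against 0.0145%, 0.0142% against 0.0111% and 0.0220% against 0.0110%). In aged mice it was lower in the polyploid library of mouse 1 (0.00646% against 0.009745%) and mouse 2 (0.00954% against 0.0183%). It was higher in that of aged mouse 3 (0.0274% against 0.0109%), so the share did not move with ploidy alike at both ages. In every pair that this fit keeps, the 3 young ones and aged mouse 3, the share was higher in the polyploid library. Within this fit it cannot be told apart from ploidy.

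Over both ages the same fit, whose spread comes from the young pairs and whose aged part is a single pair, gave 19 pericentral genes higher and 2 lower (median 0.73, adjusted p = 7.95e-09) and 3 periportal genes higher and 18 lower (median -0.47, adjusted p = 2.50e-06). With an estimated correlation both had adjusted p = 0.601. In all 12 libraries without the block the pericentral list passed in the same direction (adjusted p = 3.78e-11). The periportal list did not pass there, and its positive direction was only relative to other genes (adjusted p = 0.827). The periportal call over both ages therefore holds in the smaller fit and not in the reported one. Hepcidin, Hamp, was at 1.70 in the smaller fit and at 1.76 (adjusted p = 0.0508) in the 12 libraries, and the ketosteroid reductase Akr1c6 at 1.61 and at 1.66 (adjusted p = 0.0240).

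The pericentral genes and the 77 ribosomal protein genes lay higher in polyploid cells within mice, the latter with a median of 0.70 over both ages and 48 of 77 past the threshold with the block, but with medians over both ages of -0.08 and in aged mice of -0.97 when scaled to the hepatocyte identity genes. In the smaller fit the pericentral median within young mice exceeded the periportal one by 0.916, with opposite signs. A permutation of this difference shuffled genes and not mice, and neither list passed there with an estimated correlation. That fit had no exon length correction. With the correction and the block in all libraries, the young pericentral list passed (adjusted p = 0.000208). The young periportal list did not (adjusted p = 0.353). Dilution of hepatocyte RNA by other cells, together with a trend with exon length, was not tested. Dilution therefore stays open for the pericentral genes of young mice. A trend with exon length (rho of -0.45 in young mice) as the whole cause is argued against by adjusted p = 1.71e-10 for the pericentral list with the exon length correction and the block (adjusted p = 0.611 with the block and an estimated correlation) and by a median of 0.514 (quartiles 0.381 and 0.633) for the ribosomal protein genes. The mitochondrially encoded genes of young mice had a median of 0.51 (quartiles 0.165 and 0.666, adjusted p = 0.0161) with the block and of -0.00923 (quartiles -0.169 and 0.184, adjusted p = 0.716) with the block and the correction, and adjusted p = 0.849 with the correction alone, which is consistent with a trend with exon length. Dilution stays open for the ribosomal protein genes and for aged mice as well. Under the other-cell covariate the pericentral list turned (adjusted p = 0.246 in young mice, 0.164 in aged mice and 0.163 over both ages). That covariate parts the fractions and decides nothing. A difference of ploidy itself or of liver zone stays open too and was not tested.

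In both fractions 10 genes had every library of one age at least 4 times above every library of the other: Cdh19, Gm4788, Gm6969, Cyp2c39, Metap1d, Gm33370, Gt(ROSA)26Sor, Gm30146, Gdpd3 and Pcdh11x. Gt(ROSA)26Sor (chromosome 6, 113067428 to 113077333) was at 0.0489 to 0.573 CPM in young and 2.39 to 9.73 CPM in aged libraries. The 10 splits of the mice are too few for a share under 0.05, with 10 such genes between the ages and at most 0 in the other splits. A genetic difference between the young and the aged mice cannot be told apart from its absence by the 0 of 10 with another of them within 2 Mb (0.251 for random genes), and age itself stays open as well.

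For the number of genes with ploidy over both ages no other split gave as many, with 1219 against at most 636 in 100 splits drawn of 200. It was at most 479 in the 32 that part every pair, and with the block 3385 stood against at most 666. The real grouping is 1 of these 32, the smallest share they can give, under 0.05 but not adjusted over the split tests. The splits with 636 and 479 genes keep aged diploid replicates 1 and 2 together, and that with 479 exchanges the fractions of young mouse 3 alone. Without the block, most other splits that keep these replicates together gave 0 genes. With the block, every split that exchanged the fractions of an aged mouse gave 0 genes. Splits that exchanged young mice alone gave up to 666 (young mouse 3), with 189 for all 3 young mice and 0 for young mice 1 and 2. The number over both ages thus depended on the grouping of the aged libraries. For the number of lists over both ages chance cannot be excluded, with 25 against at most 28 both in the 100 splits, of which 16 give as many and most leave pairs together, and in the 32 that part every pair, of which 8 do. Elsewhere the splits are too few for a share under 0.05. Numbers of genes were 552 against at most 0 in diploid aging, 5 against 0 in polyploid aging, 0 against 0 in young mice, 1363 against 1 in aged mice and 0 against 0 in the interaction, and with the block 76 against 0 in young and 2214 against 0 in aged mice (4 splits each). Numbers of lists were 26 against 29, 8 against 20, 8 against 16 and 23 against 28 in the first 4 of these, and in the 4 splits that part every pair 8 against 8 in young and 23 against 28 in aged mice.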
